A study of Homo sapiens with 37 samples.

How the data were processed

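Total RNA of 37 human libraries was sequenced after ribosomal RNA was removed. Per the labels' protocols, HAEC and HUVEC grew in endothelial media and the fibroblasts in DMEM with 10% serum, and the cDNA was made with the Ovation RNA-seq System V2 and the library with a TruSeq ChIP kit. The labels state paired-end reads of 150 bases for 25 libraries; for the other 12, the second WI-38 set, no such line is given. Per the labels, HAEC were at population doubling level 4 to 6 and HUVEC at 3 to 5.

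The authors deposited 1 table of whole-number read counts per gene and library, not normalized, per the labels. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.4, featureCounts and the hg19 genome. Their settings, the annotation release and whether strand was used in counting are not given in the sources used here. The files hold 57773 Ensembl gene identifiers, of which 51996 matched the table of gene names and 52338 were given a symbol, from GENCODE release 29 where that table gave none. XIST, TSIX and genes of the Y chromosome, 474 identifiers, were left out of all tests and are not reported here. Of 329 genes that qualified to be named, 11 shared 50% or more of their exon sequence, in stretches of 31 bases, with other genes, and exons of 100 overlapped a gene on the opposite strand and those of 35 a gene on the same strand. The counts of these genes are uncertain, and 5 genes had no entry to check.

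Libraries were grouped by their labels. Each comparison was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM scaling, filterByExpr and a Benjamini-Hochberg adjusted p below 0.05, in a fit over all libraries of the same set (HAEC, HUVEC, IMR-90, the first or the second WI-38 set), so that the groups of a set share 1 estimate of the spread. Standard errors are the size of the log2 fold change divided by the square root of F. For 8 pairs of comparisons the difference of the responses was tested in 1 fit of the sets that hold them. Lists of genes, 18 in all, were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for naming genes: CDK inhibitors, p53 targets, DNA replication, mitosis, replication-dependent histones, nuclear lamina and chromatin, inflammatory secretome, proteases and growth factors, interferon-stimulated genes, extracellular matrix, lysosome, cholesterol synthesis, MAPK feedback and targets, and markers of endothelium, fibroblasts, smooth muscle, epithelium and leukocytes. Of the listed genes, 17 histone genes, UHRF1, MMP12 and PECAM1 matched no symbol in the files.

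The direction of each list was tested with fry in limma 3.58.1 on voom values, adjusted over all 162 tests, of which 123 passed. The fry test does not compare a list with other genes, and on voom weights its p depends on the order of the design columns, kept alphabetical here. Where all libraries of a group had a count of 0, a fold is given as a lower bound with 3 counts per library as the floor, which covers counting error only.

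Genes were named by rule: 12 of 13 markers of senescence fixed beforehand, in every comparison, and HRAS in its own; the 5 highest and 5 lowest fold changes among called genes with a symbol and an average log2 CPM of at least 1; the 2 called members of each list with the smallest adjusted p per direction; up to 10 shared genes per direction; and for each difference the 5 genes with the smallest adjusted p per side. Some genes that met the rule are not reported here. Genes given for groups at 0 (CSF2, CDH1 and ESRP1) and those of the closing tests were named outside the rule, after their values were seen.

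On simulated counts with 200 changed genes the test recovered, of the genes changed 4-fold, 87.9% in HAEC, 92.6% in HUVEC, 73.4% in the first doxorubicin experiment and 46.2% in irradiated WI-38, with 0 in the wrong direction. Unchanged genes made up 1.92% to 10.2% of the calls, over 5% in HAEC, in HUVEC, with HRAS and in 4 of the 8 differences. In irradiated WI-38 it recovered 8.51% of genes changed 2-fold. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 8.49 to 533, and their log2 CPM had a Pearson r across genes of 0.977 to 0.999.

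Alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0's Wald test, a fit of the compared groups only, a fit of all 37 libraries, the replicate number as a term, each library left out in turn, both doxorubicin experiments in 1 fit, and for shared genes a call in at least 8 comparisons or each comparison left out. With 1 library of a group left, it was taken to vary like the other groups of its set.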

Results

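The 37 libraries hold total RNA of human cells in 17 groups. IMR-90 and WI-38 are fibroblast strains from fetal lung, and HAEC and HUVEC are endothelial cells of the aorta and the umbilical vein. Senescence is a lasting stop of cell division, here not measured. It was sought by ionising radiation, doxorubicin, which damages DNA, a mutant HRAS delivered with a virus, or repeated passage. Each treated group was set against control cells of the same kind, in 9 comparisons. Genes that moved alike in all 9, sought as a signature of senescence, were counted too. HAEC gave 2 control and 3 irradiated libraries (4 Gy), and HUVEC 3 of each (4 Gy). Every fibroblast group held 2 libraries. IMR-90 cells were irradiated (10 Gy) or grown to population doubling level 52, and both were compared with the same 2 libraries of proliferating cells at level 15. WI-38 cells were treated with doxorubicin (2 µg/mL for 24 h) in a first experiment and again in a repeat, given mutant HRAS or an empty vector, irradiated (10 Gy), or grown to level 53 to 55 and compared with level 25.

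Library totals ran from 102293388 to 370996204 counts. The 25 libraries of HAEC, HUVEC, IMR-90 and the first WI-38 experiments held 50.7% to 66.9% of their counts in protein-coding genes. They held 4.92% to 7.48% in small RNAs recognised by symbol, namely 7SL and 7SK with their pseudogenes, RMRP and RPPH1. The 12 libraries of the WI-38 repeat, irradiation and late-passage experiments held 82.0% to 91.1% and 0.0207% to 0.138%, with 3.21% to 14% in mitochondrial genes against 0.101% to 0.607%. These 2 kinds of library never met within 1 comparison. The coefficient of variation between replicates, as edgeR estimated it, was 5.66% in HAEC, 6.92% in HUVEC, 8.40% in IMR-90, 16.3% in the first WI-38 set and 38.1% in the second. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are CPM, counts relative to the scaled library total within each set, as mean ± SD, and fold changes are log2 of treated over control, ± the standard error where one is given. For each gene list the brackets give how many of its measured members edgeR called higher (up) or lower (down) among all genes, their median log2 fold change and the q of the fry test, which asks whether the genes of a list move, on balance, one way. A q is a p-value adjusted by the Benjamini-Hochberg method. Where leaving out 1 library ended a call, brackets hold the number of libraries that did so, 1 at a time. Libraries are named by group and replicate number.

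The first comparison asked what irradiation changed in aortic endothelium. VCAM1 (ENSG00000162692), which holds leukocytes on the vessel wall, rose from 0.341 ± 0.0164 CPM (SD, n = 2) in control HAEC to 12 ± 0.775 (SD, n = 3) after 4 Gy, and SELP (ENSG00000174175), a selectin, from 0.418 ± 0.0789 to 14.8 ± 1.15. With GJA4 (ENSG00000187513, 5.65 ± 0.17), SULF1 (ENSG00000137573, 5.31 ± 0.08), and GALNT15 (ENSG00000131386, 4.25 ± 0.07), they had the 5 highest fold changes. The collagenase MMP1 (ENSG00000196611) fell from 5052 ± 62 to 422 ± 19.7 CPM (-3.58 ± 0.03), and ADTRP (ENSG00000111863, -3.16) and PRSS3 (ENSG00000010438, -2.96) fell too. WTAPP1 (ENSG00000255282, -3.59) lies on the strand opposite MMP1 and MMP3 (ENSG00000149968), so reads where they overlap cannot be told apart. MMP3 (-5.06) and IL1B (ENSG00000125538, -4.06) passed as lower, but their control values of 5.06 ± 6.94 and 0.821 ± 0.962 CPM came almost wholly from control replicate 1. Without it MMP3 stood at 0.04 (edgeR q = 0.976) and IL1B at -1.49 (edgeR q = 0.270).

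All 28 mitosis genes fell (median -1.44, fry q = 4.98e-05), led by TOP2A (ENSG00000131747, -1.64), and so did all 27 DNA replication genes (median -1.24, q = 2.75e-05), among them RRM2 (ENSG00000171848, -1.74). The 8 measured histone genes (median -1.85, fry q = 3.49e-05), such as H1-5 (ENSG00000184357, -2.15), the 19 lamina and chromatin genes (median -0.96, q = 4.22e-05) and the 20 cholesterol synthesis genes (median -0.66, q = 3.13e-04) all fell. The p53 targets rose (20 up, 2 down of 25, median 0.70, fry q = 1.50e-04), such as TP53INP1 (ENSG00000164938, 1.49). Interferon-stimulated genes rose (23 up, 1 down of 25, median 1.22, fry q = 0.0159), with IFI27 (ENSG00000165949, 3.58) and IFI6 (ENSG00000126709, 2.47) up and ISG20 (ENSG00000172183, -1.93) down. Lysosome genes rose (19 up, 3 down of 25, median 0.39, fry q = 6.61e-04), such as NPC2 (ENSG00000119655, 0.67), as did the inflammatory secretome (10 up, 3 down of 18, median 0.52, q = 9.79e-04), with IL32 (ENSG00000008517, 2.44) up and CSF3 (ENSG00000108342, -2.36) down. The matrix list tested higher (13 up, 4 down of 25, median 0.13, fry q = 0.00356), with POSTN (ENSG00000133110, 1.03) and THBS1 (ENSG00000137801, 0.60) up. MAPK targets fell (2 up, 12 down of 19, median -0.44, fry q = 2.88e-04), among them DUSP4 (ENSG00000120875, -1.28). The protease and growth factor list tested lower (10 up, 12 down of 24, median -0.31, fry q = 0.0135), with IGFBP7 (ENSG00000163453, 1.18) up and PLAT (ENSG00000104368, -2.25) down. The CDK inhibitor list tested lower (3 up, 3 down of 7, median -0.01, fry q = 0.0291), with CDKN2C (ENSG00000123080, -1.53) down and CDKN1C (ENSG00000129757, 1.80) up.

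Markers of endothelium tested higher (7 up, 4 down of 14, median 0.19, fry q = 0.00501), with VWF (ENSG00000110799, 1.53) highest, and so did those of epithelium (4 up of 6, median 0.40, q = 2.04e-04), with KRT7 (ENSG00000135480, 1.68), and of smooth muscle (3 up, 1 down of 9, median 0.03, q = 0.0152), with TAGLN (ENSG00000149591, 0.89). The fry test did not pass for the fibroblast (5 down of 15, median -0.44, q = 0.237) and leukocyte (1 up, 1 down of 4, median 0.34, q = 0.325) lists. The leukocyte median and mean lay above 0 while the test pointed down. Of the 12 genes followed in every comparison, CDKN1A (ENSG00000124762, 0.56), CDKN2B (ENSG00000147883, 0.27), IL6 (ENSG00000136244, 0.43), CXCL8 (ENSG00000169429, 0.30), GDF15 (ENSG00000130513, 1.40), MDM2 (ENSG00000135679, 0.82) and GLB1 (ENSG00000170266, 0.26) rose. LMNB1 (ENSG00000113368, -1.24), HMGB2 (ENSG00000164104, -1.29) and MKI67 (ENSG00000148773, -1.54) fell, IL1B only with control 1. CDKN2A (ENSG00000147889, -0.01, q = 0.928) did not pass edgeR. edgeR called 5526 genes higher and 5583 lower of 27974 (adjusted p below 0.05), 1338 and 920 by at least 2-fold. With all 37 libraries it called 2319 and 1622. Adjusted over the list alone, counts differed for the p53 target (21 up, 2 down), interferon (24 up, 1 down), matrix (13 up, 5 down), endothelial (8 up, 4 down), fibroblast (3 down) and smooth muscle (3 up, 2 down) lists. Leaving out 1 library ended the fry call of the CDK inhibitor (3), protease (2), interferon (3) and smooth muscle (3) lists, q 0.0516 to 0.131. The edgeR calls of CDKN2B (1), IL1B (1) and MMP3 (1) ended too. Calls also ended with no filter for the CDK inhibitor and protease lists (fry q 0.0786 to 0.0914), and with all 37 libraries for the smooth muscle list (fry q = 0.302) and CDKN2B, CXCL8, GLB1 and IL6 (edgeR q 0.122 to 0.685).

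The same dose was given to venous endothelium. GALNT15 rose from 1.5 ± 0.405 CPM (SD, n = 3) in control HUVEC to 17.1 ± 0.326 (SD, n = 3) after irradiation (3.51 ± 0.11), and PKHD1L1 (ENSG00000205038) from 3.89 ± 0.257 to 27.8 ± 0.284 (2.84 ± 0.06). The interferon-stimulated gene IFI44L (ENSG00000137959) rose from 1.02 ± 0.259 to 6.38 ± 0.228. CADM3 (ENSG00000162706, 2.49) and the antisense gene CADM3-AS1 (ENSG00000225670, 2.49) rose as well, and reads where they overlap cannot be told apart without strand. The lowest were LITAF (ENSG00000189067, -2.54), PTPRD (ENSG00000153707, -2.46), CSGALNACT1 (ENSG00000147408, -2.04), CPE (ENSG00000109472, -1.97) and TFPI2 (ENSG00000105825, -1.73).

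All 28 mitosis genes fell (median -0.69, fry q = 2.08e-04), such as CENPE (ENSG00000138778, -0.86), and so did all 27 DNA replication genes (median -0.74, q = 3.49e-05), such as FEN1 (ENSG00000168496, -1.26) and RRM2 (-1.13). Histone (8 down of 8, median -0.76, fry q = 2.75e-05), lamina and chromatin (18 down of 19, median -0.54, q = 2.28e-04) and cholesterol synthesis genes (1 up, 17 down of 20, median -0.27, q = 0.00144) fell, such as H4C3 (ENSG00000197061, -1.01), NCAPG (ENSG00000109805, -0.91) and HMGCS1 (ENSG00000112972, -0.62). The p53 target list rose (22 up, 2 down of 25, median 0.78, fry q = 1.78e-05), led by ZMAT3 (ENSG00000172667, 1.29) and TP53INP1 (1.23), and the CDK inhibitor list rose with it (5 up, 2 down of 7, median 0.45, q = 4.22e-05). Interferon-stimulated genes (19 up, 1 down of 24, median 0.68, fry q = 6.68e-05), such as IFI27 (1.13), and lysosome genes (19 up, 2 down of 25, median 0.38, q = 5.65e-05) rose, and the inflammatory secretome tested higher (7 up, 1 down of 18, median 0.20, q = 4.76e-04), with ICAM1 (ENSG00000090339, 1.85). Matrix genes rose (13 up of 25, median 0.22, fry q = 0.00273), COL12A1 (ENSG00000111799, 1.26) most clearly. MAPK targets tested lower (3 up, 9 down of 19, median -0.17, fry q = 2.88e-04), with EMP1 (ENSG00000134531, -0.74). Epithelial markers tested higher (2 up of 7, median 0.01, fry q = 9.15e-04), with KRT7 (0.75).

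No fry call was made for the protease (6 up, 8 down of 24, median -0.15, q = 0.0509), endothelial (5 up, 4 down of 14, median 0.06, q = 0.442), fibroblast (2 up, 1 down of 15, median -0.26, q = 0.842), smooth muscle (2 up, 2 down of 9, median 0.07, q = 0.0959) and leukocyte (1 down of 5, median -0.10, q = 0.0799) lists. Median, mean and test differed in sign for the last 3. Of the genes followed throughout, CDKN1A (0.89), CDKN2A (1.31), CDKN2B (0.45), IL6 (0.23), GDF15 (0.77), MDM2 (0.62) and GLB1 (0.47) rose. LMNB1 (-0.60), HMGB2 (-0.36), MKI67 (-0.55) and CXCL8 (-0.47) fell. IL1B (-0.69, q = 0.410) did not pass edgeR. The edgeR test called 5129 genes higher and 5508 lower of 27478, 590 and 357 by at least 2-fold. A fit of all 37 libraries called 1435 and 1825. Counts adjusted over the list alone differed for the lamina (19 down), protease (6 up, 9 down), matrix (14 up, 1 down) and lysosome (20 up, 2 down) lists. With 1 library left out, edgeR no longer called IL6 (4), q 0.0561 to 0.180. Other fits ended calls, with all 37 libraries for the inflammatory, matrix and epithelial lists (fry q 0.0509 to 0.114) and CDKN2B, CXCL8, HMGB2, IL6 and MKI67 (edgeR q 0.0633 to 0.568). A fry call was gained by the protease list with size factors, the smooth muscle list with no filter, the endothelial list without control 1 and the leukocyte list without control 2 (q 0.00697 to 0.0303).

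IMR-90 fibroblasts given 10 Gy were compared with proliferating cells. Chemokines of the CXC family fell: CXCL8 from 134 ± 10.3 CPM (SD, n = 2) to 3.88 ± 0.382 (SD, n = 2), CXCL1 (ENSG00000163739) from 82.0 ± 0.775 to 0.256 ± 0.0669, and CXCL6 (ENSG00000124875) from 22.8 ± 0.0513 to 0.0438 ± 0.0268. ADH1B (ENSG00000196616, -8.93) and the growth factors FGF10 (ENSG00000070193, -7.46) and BMP5 (ENSG00000112175, -7.29) had, with CXCL6 and CXCL1, the 5 lowest fold changes. The cyclin CCND1 (ENSG00000110092) rose from 105 ± 0.691 to 1774 ± 22.2 CPM (4.08 ± 0.06). The highest fold changes were those of NLRP10 (ENSG00000182261, 8.90), KISS1 (ENSG00000170498, 8.61), OSTN-AS1 (ENSG00000233308, 7.81), SERPINB7 (ENSG00000166396, 7.14) and KRTAP1-5 (ENSG00000221852, 7.07).

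Protein-coding genes held 64.8% and 61.5% of counts in proliferating, 57.9% and 56.9% in irradiated and 61.1% and 62.5% in late-passage libraries. Mitosis genes rose (26 up of 28, median 0.70, fry q = 5.88e-04), with AURKA (ENSG00000087586, 1.88), and DNA replication genes rose (26 up of 27, median 0.81, q = 0.00206), with RRM2 (1.71) and E2F1 (ENSG00000101412, 2.11). The lamina and chromatin list tested higher (9 up, 3 down of 19, median 0.18, fry q = 0.0116), with LMNA (ENSG00000160789, 1.36) and NCAPG (0.91) up. The p53 target list rose (20 up, 1 down of 25, median 0.84, fry q = 0.00842), with FAS (ENSG00000026103, 1.91), while PLK2 (ENSG00000145632, -2.62) fell. The inflammatory secretome fell (2 up, 17 down of 20, median -3.73, fry q = 5.51e-04), although IL11 (ENSG00000095752, 1.77) rose. CSF2 (ENSG00000164400) had no count in the proliferating libraries and was at least 10.2-fold higher. Proteases and growth factors tested higher (14 up, 9 down of 24, median 0.76, fry q = 0.0112), with PLAUR (ENSG00000011422, 2.25) up and EREG (ENSG00000124882, -3.16) down, as did MAPK targets (13 up, 5 down of 19, median 1.05, q = 5.51e-04), with HBEGF (ENSG00000113070, 4.04), and cholesterol synthesis genes (17 up, 2 down of 20, median 0.67, q = 1.96e-04). Matrix genes fell (6 up, 14 down of 25, median -0.71, fry q = 0.00584), such as THBS2 (ENSG00000186340, -3.07), although THBS1 (2.64) rose.

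Fibroblast markers fell (1 up, 14 down of 15, median -1.01, fry q = 3.13e-04), COL3A1 (ENSG00000168542, -3.67) most. Smooth muscle markers tested higher (6 up, 3 down of 10, median 0.80, fry q = 0.0119), with TAGLN (2.09) up and MYOCD (ENSG00000141052, -4.83) down, epithelial markers rose (6 up of 8, median 2.19, q = 0.00273, or a median of 2.15 with CDH1, at 0 in controls, at its bound), with KRT19 (ENSG00000171345, 5.19), and leukocyte markers tested higher (2 up of 6, median 0.99, q = 0.0110), with CD68 (ENSG00000129226, 0.86), 81.3% of whose exon sequence is shared with other genes. Not passing were the CDK inhibitor (4 up, 3 down of 7, median 0.27, q = 0.0674), histone (1 up, 5 down of 8, median -0.23, q = 0.375), interferon (12 up, 7 down of 25, median 0.54, q = 0.0516), lysosome (11 up, 7 down of 25, median 0.11, q = 0.209) and endothelial (3 up, 2 down of 14, median -0.02, q = 0.805) lists. Median, mean and test differed in sign for the CDK inhibitor and endothelial lists. Among the 12 genes followed throughout, CDKN1A (1.82), CDKN2A (1.64), CDKN2B (0.27), MKI67 (0.67), GDF15 (1.67) and MDM2 (1.22) rose. IL6 (-1.38), CXCL8 (-5.11) and IL1B (-4.58) fell. LMNB1 (0.03, q = 0.863), HMGB2 (0.18, q = 0.171) and GLB1 (0.04, q = 0.639) did not pass edgeR. edgeR called 7788 genes higher and 6580 lower of 29247, 2496 and 2707 by at least 2-fold. A fit of all 37 libraries called 9126. Adjusted over the list alone, no list had other counts. With 1 library left out, the fry test did not pass for the p53 target (2), lamina (4), protease (3), smooth muscle (2) and leukocyte (3) lists, q 0.0509 to 0.842. The edgeR call was lost for CDKN2B (2), q 0.0640 to 0.128. HMGB2 passed with no filter or the compared groups only (edgeR q 0.0248 to 0.0269). Among other fits, calls ended with no filter for the leukocyte list (fry q = 0.120), and with all 37 libraries for the smooth muscle and leukocyte lists (fry q 0.603 to 0.899) and CDKN2B (edgeR q = 0.263). Fry calls were gained by the CDK inhibitor list with no filter, the lysosome list with all 37 libraries and the interferon list without irradiated 1 or 2 (q 0.0159 to 0.0469). The CDK inhibitor list with the compared groups only turned upward and passed (q = 0.00905).

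IMR-90 cells at doubling level 52 were compared with the same proliferating libraries at level 15. IGFBP7 rose from 186 ± 17.2 CPM (SD, n = 2) to 1719 ± 221 (SD, n = 2). CDKN2A, a cell-cycle inhibitor, rose from 4.16 ± 0.0427 to 24.2 ± 6.64 (2.54 ± 0.14). The highest fold changes were those of TMEM178B (ENSG00000261115, 10.33), NLRP10 (9.18), KISS1 (8.20), OSTN-AS1 (8.19) and TRIM55 (ENSG00000147573, 8.07), and the lowest those of CXCL6 (-9.46), BMP5 (-9.30), ADH1B (-9.12), CXCL1 (-8.99) and CXCL3 (ENSG00000163734, -8.45).

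Mitosis genes tested higher (12 up, 3 down of 28, median 0.13, fry q = 0.0116), AURKA (1.34) rising and TOP2A (-0.40) falling, as did DNA replication genes (19 up, 1 down of 27, median 0.42, q = 0.0150), with E2F1 (1.71) and RRM2 (0.97) up. Histone genes fell (6 down of 8, median -0.56, fry q = 0.0413), with H1-4 (ENSG00000168298, -1.14). The p53 targets tested higher (16 up, 1 down of 25, median 0.47, fry q = 0.0175), with FAS (1.73). The inflammatory secretome fell (2 up, 16 down of 20, median -3.77, fry q = 9.33e-04). Its exceptions were IL11 (1.24) and CSF2, at least 6.22-fold higher. CSF2 at its bound left both IMR-90 medians the same. Cholesterol synthesis genes (17 up, 1 down of 20, median 0.91, fry q = 8.01e-05), MAPK targets (13 up, 5 down of 19, median 1.10, q = 3.02e-04), such as CCND1 (4.11) and HBEGF (4.01), and the protease and growth factor list (13 up, 10 down of 24, median 0.53, q = 0.0128), with VEGFA (ENSG00000112715, -2.18) down, tested higher. Fibroblast markers fell (2 up, 11 down of 15, median -0.97, fry q = 6.61e-04), with COL3A1 (-3.07) down. Smooth muscle (6 up, 4 down of 10, median 1.15, fry q = 0.00618), epithelial (6 up, 1 down of 8, median 1.84, q = 0.00477) and leukocyte markers (2 up of 6, median 0.73, q = 0.0150) tested higher, with TAGLN (2.31), KRT18 (ENSG00000111057, 2.65) and CD68 (0.53) as members; MYOCD (-3.60) fell.

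The fry test missed its threshold for the CDK inhibitor (4 up, 3 down of 7, median 0.84, q = 0.204), lamina (8 up, 8 down of 19, median -0.08, q = 0.181), interferon (7 up, 11 down of 25, median -0.20, q = 0.0861), matrix (10 up, 11 down of 25, median -0.04, q = 0.0538), lysosome (11 up, 7 down of 25, median 0.15, q = 0.824) and endothelial (3 up, 8 down of 14, median -0.70, q = 0.251) lists. Median, mean and test differed in sign for the CDK inhibitor, lamina and lysosome lists. Of the 12 fixed genes, CDKN1A (1.42), CDKN2A (2.54), CDKN2B (0.84), MDM2 (0.85) and GLB1 (0.16) rose. LMNB1 (-0.44), HMGB2 (-0.38), IL6 (-0.81), CXCL8 (-6.23) and IL1B (-5.46) fell. MKI67 (0.11, q = 0.419) and GDF15 (-0.46, q = 0.0878) did not pass edgeR. By edgeR 7783 genes were higher and 6876 lower of 29247, 2556 and 2967 by at least 2-fold. With all 37 libraries 9318 passed. Adjusted over the list alone, counts differed for the histone (7 down), interferon (7 up, 12 down), lysosome (11 up, 8 down) and fibroblast (2 up, 12 down) lists. Leaving out 1 library ended the fry call of the p53 target (2), DNA replication (2), mitosis (2), histone (4), protease (2), smooth muscle (2) and leukocyte (2) lists, q 0.0578 to 0.240. Of the genes named, edgeR no longer called GLB1 (3), HMGB2 (1) and IL6 (1), q 0.0662 to 0.255. GDF15 stood at -1.09 without late-passage 1 (edgeR q = 2.78e-11) and MKI67 at 0.26 without late-passage 2 (edgeR q = 0.021), and with no filter GDF15 passed (edgeR q = 4.57e-11). Calls also ended with the compared groups only for the p53 target, DNA replication and histone lists (fry q 0.0513 to 0.10) and GLB1 (edgeR q = 0.0837), and with no filter for the leukocyte list (fry q = 0.120), and with all 37 libraries for the smooth muscle and leukocyte lists (fry q 0.0781 to 0.645) and GLB1, HMGB2, LMNB1 and TOP2A (edgeR q 0.176 to 0.335). A fry call was gained by the matrix list with no filter or without proliferating 1 or 2, the interferon list with the compared groups only and the lamina list without late-passage 2 (q 0.0112 to 0.0368). The CDK inhibitor list without late-passage 1 or 2 turned upward and passed (q 1.75e-04 to 0.00144).

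Across genes the 2 IMR-90 responses had a Pearson r of 0.960, where simulated unchanged groups set against the same 2 controls gave 0.506 on average and at most 0.520. Genes are not independent replicates. The covariance was 0.873 against a simulated 0.00576. Both responses called 6730 genes higher and 5317 lower, where independent lists would share 2072 and 1547. The simulated groups shared 0.1 and 0, being unchanged. The 2 control libraries were not split, so all or part of the excess may come from the shared controls.

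In WI-38 fibroblasts the first doxorubicin experiment asked what DNA damage by this drug changed. CXCL8 rose from 6.88 ± 3.51 CPM (SD, n = 2) to 322 ± 28.1 (SD, n = 2) and IL6 from 2.46 ± 0.0618 to 23.2 ± 0.333. C3 (ENSG00000125730, 8.34) and the chemokines CXCL1 (8.20), CXCL6 (7.52), CXCL5 (ENSG00000163735, 6.43) and CXCL3 (5.60) had the highest fold changes. MKI67, a mark of dividing cells, fell from 55.8 ± 2.64 to 1.66 ± 0.193 CPM, and LMNB1, a protein of the nuclear lamina, from 84.5 ± 0.615 to 3.13 ± 0.278 (-4.75 ± 0.14). The lowest fold changes were those of ENSG00000231864 (-5.72), 96.2% of whose sequence is shared with another gene, and the histone genes H1-5 (-5.70), H3C13 (ENSG00000183598, -5.66), H3C14 (ENSG00000203811, -5.51) and H3C15 (ENSG00000203852, -5.51), of which H3C14 and H3C15 share all of their exon sequence with other genes.

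Mitochondrial genes held 0.123% and 0.186% of counts in controls and 0.245% and 0.341% in treated libraries. All 28 mitosis genes fell (median -4.01, fry q = 1.78e-05), such as KIF20A (ENSG00000112984, -4.56), as did all 27 DNA replication genes (median -2.45, q = 1.40e-05), such as MCM10 (ENSG00000065328, -4.77) and RRM2 (-3.90), all 8 listed histone genes (median -4.20, q = 8.54e-05) and all 19 lamina and chromatin genes (median -2.02, q = 4.22e-05). The p53 target list rose (18 up, 1 down of 25, median 0.69, fry q = 3.77e-05), with GDF15 (1.95) and CDKN1A (1.72). The inflammatory secretome rose (19 up of 21, median 3.24, fry q = 1.10e-04), and with it proteases and growth factors (17 up, 2 down of 24, median 0.93, q = 1.40e-05), such as MMP3 (3.17), interferon-stimulated genes (13 up of 25, median 0.85, q = 6.61e-04), such as IFI6 (2.4), and lysosome genes (18 up of 25, median 0.75, q = 8.73e-05), such as CTSK (ENSG00000143387, 1.95). Fibroblast markers tested higher (6 up, 3 down of 15, median 0.29, fry q = 0.00204), with COL3A1 (1.10) up, and leukocyte markers too (2 up of 6, median 1.33, q = 0.00526), with CD14 (ENSG00000170458, 2.42). Smooth muscle (4 down of 10, median -0.68, fry q = 3.02e-04), with ACTA2 (ENSG00000107796, -1.57), and epithelial markers tested lower (2 up, 4 down of 9, median -0.47, q = 0.0175), with KRT19 (-1.38). Their mean was 0.47, or -0.03 with ESRP1 (ENSG00000104413), absent from controls and at least 4.52-fold higher, at its bound.

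The lists with no fry call were the CDK inhibitor (3 up, 3 down of 7, median 0.22, q = 0.209), matrix (6 up, 5 down of 25, median 0.17, q = 0.602), cholesterol (3 up, 3 down of 20, median 0.04, q = 0.924), MAPK target (5 up, 8 down of 19, median -0.30, q = 0.146) and endothelial (2 up, 8 down of 14, median -1.43, q = 0.10) lists. Median, mean and test differed in sign for the CDK inhibitor, matrix and cholesterol lists. Of the 12 genes fixed beforehand, CDKN1A (1.72), CDKN2A (0.53), CDKN2B (1.03), IL6 (3.24), CXCL8 (5.54), GDF15 (1.95), MDM2 (1.21) and GLB1 (0.71) rose. LMNB1 (-4.75), HMGB2 (-3.19) and MKI67 (-5.07) fell. IL1B (1.13, q = 0.214) did not pass edgeR. edgeR called 3989 genes higher and 3876 lower of 29358, 2190 and 1656 by at least 2-fold. With the compared groups only it called 6372 and 6325. Adjusted over the list alone, counts differed for the p53 target (18 up, 3 down), protease (18 up, 2 down), interferon (16 up, 1 down), matrix (7 up, 5 down), lysosome (21 up), cholesterol (3 up, 4 down), MAPK target (5 up, 9 down), fibroblast (6 up, 4 down), smooth muscle (6 down) and leukocyte (3 up) lists. The number of called genes was 4485 to 4745 with any 1 library left out. Without 1 library the fry call was lost for the epithelial (2) list, q 0.0523 to 0.0930. Among these genes, the edgeR call ended for CDKN2A (4), q 0.0584 to 0.170. IL1B stood at 4.00 without control 2 (edgeR q = 2.5e-07) and passed with no filter (edgeR q = 1.74e-11). Other fits ended calls, with the compared groups only for the epithelial list (fry q = 0.0513), and with no filter for the epithelial list (q = 0.104), and with all 37 libraries for the epithelial and leukocyte lists (fry q 0.0683 to 0.315). Fry calls were gained by the matrix list with the compared groups only and the CDK inhibitor and endothelial lists with all 37 libraries (q 1.95e-04 to 0.00927). The CDK inhibitor and MAPK target lists with the compared groups only turned upward and passed (q 0.0117 to 0.0376).

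WI-38 cells given mutant HRAS were compared with cells given the empty vector. HRAS (ENSG00000174775) itself stood at 1967 ± 31.3 CPM (SD, n = 2) against 41.6 ± 7.76 (SD, n = 2), a log2 fold change of 5.57 ± 0.17. MMP3 rose from 4.32 ± 0.625 to 3705 ± 147 CPM, IL1B from 0.734 ± 0.0683 to 539 ± 0.0990, and CXCL8 from 1.94 ± 0.0462 to 1291 ± 412. The chemokine gene CCL20 (ENSG00000115009) had no count in empty-vector cells and was at least 969-fold higher at 18.6 ± 3.70 CPM, and LINC02154 (ENSG00000235385, 10.19) and LCE1F (ENSG00000240386, 9.72) were also among the 5 highest. TMEM119 (ENSG00000183160) fell from 31.5 ± 5.36 to 0.348 ± 0.0717 CPM, and with COL15A1 (ENSG00000204291, -7.24), TOX (ENSG00000198846, -6.65), WNT2 (ENSG00000105989, -6.40) and C7 (ENSG00000112936, -6.22) had the lowest fold changes.

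The CDK inhibitor list rose (4 up, 3 down of 7, median 1.21, fry q = 1.99e-04), with CDKN2B (3.66) and CDKN1A (2.4) up and CDKN2C (-3.34) down. Mitosis genes fell (27 down of 28, median -2.47, fry q = 5.65e-05), such as KIF20A (-3.62), and so did DNA replication genes (25 down of 27, median -1.67, q = 2.58e-05), such as MCM10 (-2.96), histones (8 down of 8, median -3.42, q = 1.59e-04), such as H1-3 (ENSG00000124575, -3.95), and lamina and chromatin genes (14 down of 19, median -0.70, q = 3.85e-04), such as LMNB1 (-3.63). MAPK targets rose (15 up of 19, median 1.65, fry q = 2.32e-05), such as TFPI2 (4.12), as did p53 targets (19 up of 25, median 0.98, q = 1.70e-05), GDF15 (4.96) most clearly. The inflammatory secretome rose (17 up, 1 down of 21, median 5.24, fry q = 4.22e-05, the same median with the 2 members that have a bound at it), with CXCL5 (9.36) and IL1A (ENSG00000115008, 7.96), while CCL2 (ENSG00000108691, -1.69) fell. Proteases and growth factors (18 up, 6 down of 24, median 1.70, fry q = 2.06e-06), with STC1 (ENSG00000159167, 5.84), lysosome genes (20 up, 1 down of 25, median 0.89, q = 4.22e-05), with NPC1 (ENSG00000141458, 2.31), and cholesterol synthesis genes (12 up, 1 down of 20, median 0.55, q = 3.02e-04), with SQLE (ENSG00000104549, 1.15), rose too. Matrix genes fell (2 up, 23 down of 25, median -1.45, fry q = 3.02e-04), such as FBLN1 (ENSG00000077942, -4.44), and interferon-stimulated genes tested lower (3 up, 11 down of 25, median -0.85, q = 0.0174), with STAT2 (ENSG00000170581, -1.23), though OASL (ENSG00000135114, 2.92) rose. Fibroblast markers (12 down of 15, median -2.12, fry q = 1.40e-05), with COL3A1 (-3.88), and smooth muscle markers (1 up, 9 down of 10, median -2.05, q = 4.22e-05), with LMOD1 (ENSG00000163431, -5.39), fell. Leukocyte markers tested higher (1 up of 6, median 1.19, fry q = 0.00206), where CD68 alone passed.

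No call came from fry for the endothelial (10 up, 2 down of 14, median 1.70, q = 0.110) and epithelial (2 up, 2 down of 9, median -0.06, q = 0.202) lists. The epithelial list had a mean of 0.09 and a median and test below 0, the mean being -0.43 with ESRP1, absent from the empty-vector cells, at its bound. Among the 12 fixed genes, CDKN1A (2.4), CDKN2A (2.25), CDKN2B (3.66), IL6 (3.77), CXCL8 (9.38), IL1B (9.52), GDF15 (4.96), MDM2 (0.52) and GLB1 (0.54) rose. LMNB1 (-3.63), HMGB2 (-2.50) and MKI67 (-3.63) fell. The edgeR test called 7951 genes higher and 5537 lower of 29358, 3896 and 3751 by at least 2-fold. Of the calls 58.9% were higher, or 48.7% (5687 higher and 6003 lower) with only the compared groups in the fit. That scaling, like all 37 libraries in the fit, moved the median of all genes by -0.14 on the log2 scale. Counts adjusted over the list alone differed for the p53 target (20 up), DNA replication (26 down), lamina (15 down), interferon (4 up, 11 down), lysosome (21 up, 1 down), cholesterol (13 up, 2 down) and endothelial (11 up, 2 down) lists. With 1 library left out, the fry test did not pass for the interferon (1) list, q = 0.110. The edgeR call was lost for MDM2 (2), q 0.159 to 0.181. Among other fits, calls ended with the compared groups only for GLB1 and MDM2 (edgeR q 0.121 to 0.143), and with all 37 libraries for the interferon and leukocyte lists (fry q 0.0661 to 0.312) and MDM2 (edgeR q = 0.0539). A fry call was gained by the endothelial and epithelial lists with all 37 libraries and the endothelial list without HRAS 1 (q 9.33e-04 to 0.0374).

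The repeat of the doxorubicin experiment used the same dose and time. The interferon-stimulated gene IFI6 rose from 30.0 ± 6.28 CPM (SD, n = 2) to 299 ± 82.4 (SD, n = 2), and the chemokine CCL2 from 8.62 ± 3.34 to 174 ± 3.06. The highest fold changes were those of CXCL6 (8.78), C3 (7.56), CXCL1 (6.32) and the fetal globin genes HBG1 (ENSG00000213934, 7.06) and HBG2 (ENSG00000196565, 6.82), 2 near-identical copies whose counts are uncertain. HMGCS1, an enzyme of early cholesterol synthesis, fell from 182 ± 19.8 to 16.6 ± 0.961 CPM (-3.45 ± 0.31), and FABP3 (ENSG00000121769, -5.73), ENSG00000261604 (-4.39), which shares 26.1% of its sequence with another gene, MVD (ENSG00000167508, -3.46) and KRT19 (-3.43) were the other lowest.

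Mitochondrial genes held 3.58% and 5.11% of counts in controls and 5.61% and 5.78% in treated libraries. Cholesterol synthesis genes fell (19 down of 20, median -1.90, fry q = 5.15e-04), with FDPS (ENSG00000160752, -2.06). Interferon-stimulated genes rose (18 up of 25, median 2.06, fry q = 0.00126), with OAS1 (ENSG00000089127, 4.71), as did the inflammatory secretome (12 up, 1 down of 21, median 3.05, q = 2.88e-04), with CXCL5 (5.50), and proteases and growth factors (16 up of 24, median 1.08, q = 2.57e-05), with MMP3 (4.01). The matrix list (6 up of 25, median 0.45, fry q = 0.0174) and the fibroblast markers (3 up, 3 down of 15, median 0.45, q = 0.00144) tested higher, COL3A1 (1.74) belonging to both. Mitosis genes (6 down of 28, median -0.62, fry q = 0.0420), with MKI67 (-1.64), and DNA replication genes (3 down of 27, median -0.41, q = 0.00401) tested lower. The lamina and chromatin list (4 down of 19, median -0.32, fry q = 0.0123), the CDK inhibitor list (1 down of 7, median -0.48, q = 0.0108) and the epithelial markers (2 down of 9, median -0.70, q = 0.00202) tested lower.

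The fry test gave no call for the p53 target (1 down of 25, median 0.04, q = 0.814), histone (1 up, 3 down of 8, median -1.16, q = 0.110), lysosome (2 up, 1 down of 25, median 0.02, q = 0.842), MAPK target (1 up, 1 down of 19, median -0.18, q = 0.110), endothelial (1 up, 1 down of 13, median 0.20, q = 0.398), smooth muscle (1 up of 10, median -0.50, q = 0.161) and leukocyte (1 up of 11, median 0.98, q = 0.132) lists. Median, mean and test differed in sign for the p53 and MAPK target lists. Of the 12 fixed genes in this comparison, IL6 (1.96), CXCL8 (3.10) and IL1B (5.06) rose. CDKN2A (-1.19), LMNB1 (-1.54), HMGB2 (-1.04) and MKI67 (-1.64) fell. CDKN1A (0.09, q = 0.877), CDKN2B (-0.96, q = 0.0557), GDF15 (0.47, q = 0.319), MDM2 (0.39, q = 0.356) and GLB1 (0.22, q = 0.650) did not pass edgeR. edgeR called 1076 genes higher and 766 lower of 33581, 831 and 513 by at least 2-fold. Of the calls 58.4% were higher, or 48.6% (3142 higher and 3326 lower) with all 37 libraries. The total was 3136 with no filter and 3576 by DESeq2's Wald test. Adjusted over the list alone, counts differed for the CDK inhibitor (2 down), DNA replication (4 down), mitosis (9 down), histone (2 up, 5 down), lamina (5 down), inflammatory (16 up, 1 down), protease (18 up), interferon (20 up), matrix (11 up), cholesterol (20 down), MAPK target (2 up, 2 down), endothelial (1 up, 2 down), fibroblast (6 up, 3 down), smooth muscle (1 up, 4 down) and epithelial (3 down) lists. The number of called genes was 612 without control replicate 1 and 952 without doxorubicin replicate 2. Leaving out 1 library ended the fry call of the CDK inhibitor (1), mitosis (3), lamina (1) and matrix (2) lists, q 0.0597 to 0.190. Of the genes named, edgeR no longer called CDKN2A (2), CXCL8 (1), HMGB2 (2), LMNB1 (2) and MKI67 (1), q 0.0533 to 0.312. CDKN2B passed without control 2 or doxorubicin 1, with no filter, with all 37 libraries and by DESeq2's Wald test (q 3.17e-04 to 0.0386). Calls also ended with the compared groups only for the DNA replication, mitosis, interferon, matrix, fibroblast and epithelial lists (fry q 0.0501 to 0.148) and HMGB2 (edgeR q = 0.05005). Fry calls were gained by the leukocyte list with the compared groups only, the histone, MAPK target, smooth muscle and leukocyte lists with all 37 libraries, the endothelial list without control 2 and the MAPK target list without doxorubicin 1 (q 0.00303 to 0.0371).

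WI-38 cells given 10 Gy were compared with their own controls. IFI6 rose from 6.63 ± 0.214 CPM (SD, n = 2) to 486 ± 21.9 (SD, n = 2), and OAS1 from 0.0375 ± 0.0124 to 36.7 ± 7.05 (9.89 ± 0.46). With OAS1, the highest fold changes were those of C3 (9.26), LINC02154 (8.79), CHI3L2 (ENSG00000064886, 8.51) and OAS2 (ENSG00000111335, 8.26). MKI67 fell from 202 ± 17.1 to 9.29 ± 2.21 CPM, and with TK1 (ENSG00000167900, -4.59), CENPF (ENSG00000117724, -4.40), NEK2 (ENSG00000117650, -5.19) and MYBL2 (ENSG00000101057, -5.30) had the lowest fold changes.

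The mitochondrial share was 6.31% and 6.99% of counts in controls and 9.71% and 14% in irradiated libraries. Interferon-stimulated genes rose (23 up of 25, median 3.57, fry q = 1.53e-04). All 28 mitosis genes fell (median -3.69, fry q = 3.13e-05), such as CDC20 (ENSG00000117399, -4.02), and so did the DNA replication (20 down of 27, median -1.31, q = 1.78e-05), histone (5 down of 8, median -2.96, q = 4.33e-04) and lamina and chromatin lists (17 down of 19, median -1.34, q = 2.57e-05), with RRM2 (-3.60), H1-5 (-4.16) and EZH2 (ENSG00000106462, -2.39) as members. Cholesterol synthesis genes fell (19 down of 20, median -2.21, fry q = 3.17e-04), with HMGCS1 (-3.41) and FDPS (-2.30). The inflammatory secretome rose (17 up of 21, median 3.80, fry q = 9.21e-05), with CCL2 (5.14), and so did proteases and growth factors (16 up of 24, median 1.20, q = 1.78e-05), with AREG (ENSG00000109321, 4.26), and lysosome genes (20 up of 25, median 1.24, q = 2.92e-04), with FUCA1 (ENSG00000179163, 2.66). The p53 (9 up of 25, median 0.38, fry q = 1.29e-04), with BTG2 (ENSG00000159388, 1.49), and MAPK targets (6 up, 1 down of 19, median 0.34, q = 0.00132), with LIF (ENSG00000128342, 2.17), tested higher. The CDK inhibitor list tested lower (1 up, 1 down of 7, median 0.06, fry q = 0.0319) with a median above 0; CDKN2C (-3.30) fell. Fibroblast markers tested higher (4 up, 1 down of 15, median 0.05, fry q = 0.0307), with TCF21 (ENSG00000118526, 1.5), and endothelial (1 up, 2 down of 13, median -0.30, q = 0.00601), smooth muscle (3 down of 10, median -0.69, q = 0.00937) and epithelial markers (2 down of 9, median -0.86, q = 0.0334) lower, with ROBO4 (ENSG00000154133, -2.4) and TAGLN (-1.5) down.

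The fry test was not passed by the matrix (5 up, 2 down of 25, median 0.18, q = 0.293) and leukocyte (1 up, 1 down of 11, median 0.00, q = 0.630) lists. The leukocyte list had a mean below 0 and a test pointing up. Among the genes followed throughout, CDKN1A (0.94), IL6 (3.63), CXCL8 (5.85), IL1B (3.56), GDF15 (2.71), MDM2 (0.87) and GLB1 (0.84) rose. LMNB1 (-2.70), HMGB2 (-1.28) and MKI67 (-4.44) fell. CDKN2A (-0.04, q = 0.925) and CDKN2B (0.24, q = 0.599) did not pass edgeR. edgeR called 2989 genes higher and 2047 lower of 33581, 2248 and 1379 by at least 2-fold. Of the calls 59.4% were higher, or 46.8% (5068 higher and 5758 lower) with all 37 libraries and 49.5% by DESeq2's Wald test. Counts adjusted over the list alone differed for the p53 target (10 up), DNA replication (24 down), lamina (18 down), protease (18 up), interferon (24 up), matrix (6 up, 2 down), lysosome (22 up), cholesterol (20 down), MAPK target (7 up, 2 down), fibroblast (5 up, 2 down), smooth muscle (6 down) and leukocyte (2 up, 1 down) lists. The number of called genes was 2572 and 2678 without control replicates 1 and 2. Without 1 library the fry call was lost for the CDK inhibitor (2), endothelial (1), fibroblast (3), smooth muscle (1) and epithelial (3) lists, q 0.0507 to 0.147. Among these genes, the edgeR call ended for CDKN1A (2), GLB1 (3) and MDM2 (3), q 0.0518 to 0.162. Other fits ended calls, with the compared groups only for the CDK inhibitor, fibroblast and epithelial lists (fry q 0.0830 to 0.137) and MDM2 (edgeR q = 0.0689), and with no filter for the CDK inhibitor list (fry q = 0.0566), and with size factors for the fibroblast list (q = 0.0747), and with all 37 libraries for the fibroblast list (q = 0.164).

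The last comparison set WI-38 cells at doubling level 53 to 55 against cells at level 25. MMP1 rose from 69.3 ± 1.26 CPM (SD, n = 2) to 933 ± 71.0 (SD, n = 2) and MMP3 from 4.67 ± 0.446 to 204 ± 44.1. The cystatin genes CST4 (ENSG00000101441, 10.10) and CST1 (ENSG00000170373, 9.19), which share 48.7% and 35.9% of their sequence with other genes, had the highest fold changes, followed by SLCO2B1 (ENSG00000137491, 5.49), PNMA2 (ENSG00000240694, 5.49) and MMP3. POSTN fell from 317 ± 13.6 to 15.5 ± 3.49 CPM, and HEPH (ENSG00000089472, -9.60), DOK5 (ENSG00000101134, -7.52), JAKMIP2 (ENSG00000176049, -6.45), CLEC14A (ENSG00000176435, -6.24) and WNT2 (-5.88) had the lowest fold changes.

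The mitochondrial share was 3.21% and 4.41% of counts at early and 5.78% and 8.71% at late passage. Interferon-stimulated genes rose (22 up of 25, median 1.96, fry q = 0.00144), with OAS1 (4.94) and IFI6 (3.71), as did proteases and growth factors (14 up, 1 down of 24, median 1.12, q = 1.40e-05), and MAPK targets tested higher (9 up, 1 down of 19, median 0.79, q = 4.04e-04), with DUSP6 (ENSG00000139318, 2.15). Mitosis genes fell (24 down of 28, median -1.87, fry q = 7.51e-04), with NUSAP1 (ENSG00000137804, -2.81), 61.6% of whose sequence is shared with other genes, and AURKA (-2.24), and DNA replication genes fell (1 up, 15 down of 27, median -0.81, q = 1.17e-04), with MCM10 (-2.74). Histones (1 up, 5 down of 8, median -2.09, fry q = 0.00972), with H1-5 (-3.59), and lamina and chromatin genes (12 down of 19, median -0.99, q = 1.29e-04), with HMGB2 (-1.97), fell too. All 20 cholesterol synthesis genes fell (median -1.74, fry q = 6.04e-04), with HMGCS1 (-3.64). The CDK inhibitor (3 down of 7, median -0.73, fry q = 0.00367), p53 target (3 down of 25, median -0.18, q = 0.0119) and matrix lists (2 up, 9 down of 25, median -0.24, q = 0.0233) tested lower, with CDKN2C (-2.64) and FBLN1 (-2.10) as members. Fibroblast markers tested lower (6 down of 15, median -0.45, fry q = 2.28e-04), with PRRX1 (ENSG00000116132, -2.01), and endothelial markers tested higher (2 up of 13, median 0.62, q = 0.00316), with ENG (ENSG00000106991, 1.89).

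Lists without a fry call were the inflammatory (2 up, 4 down of 21, median 0.02, q = 0.591), lysosome (6 up, 1 down of 25, median 0.32, q = 0.188), smooth muscle (1 up, 1 down of 10, median -0.34, q = 0.0925), epithelial (1 down of 9, median 0.93, q = 0.146) and leukocyte (2 up of 11, median 0.79, q = 0.267) lists. The inflammatory list had a median and mean above 0 and a test pointing down. Among the 12 genes fixed beforehand, IL1B (1.75) rose. LMNB1 (-3.00), HMGB2 (-1.97) and MKI67 (-3.04) fell. CDKN1A (0.26, q = 0.476), CDKN2A (-0.03, q = 0.961), CDKN2B (-0.73, q = 0.0982), IL6 (0.83, q = 0.0545), CXCL8 (-1.08, q = 0.295), GDF15 (0.70, q = 0.0815), MDM2 (-0.07, q = 0.907) and GLB1 (0.32, q = 0.379) did not pass edgeR. By edgeR 1951 genes were higher and 2293 lower of 33581, 1428 and 1522 by at least 2-fold. A fit of all 37 libraries called 9148. Counts adjusted over the list alone differed for the CDK inhibitor (1 up, 4 down), p53 target (4 down), DNA replication (1 up, 20 down), mitosis (26 down), histone (2 up, 5 down), lamina (1 up, 14 down), inflammatory (4 up, 4 down), interferon (22 up, 1 down), matrix (3 up, 9 down), MAPK target (12 up, 1 down), endothelial (3 up, 1 down), fibroblast (1 up, 6 down), smooth muscle (1 up, 4 down) and epithelial (1 up, 2 down) lists. The number of called genes was 2472 without late-passage replicate 2 and 1881 and 1950 without early-passage replicates 1 and 2. With 1 library left out, the fry test did not pass for the p53 target (3), matrix (4) and endothelial (1) lists, q 0.0593 to 0.205. The edgeR call was lost for IL1B (3), q 0.0701 to 0.318. Without late-passage 1 CXCL8 stood at -3.13, CDKN2B at -1.19 and GDF15 at 0.93, and without late-passage 2 IL6 at 1.03, all passing (edgeR q 4.07e-04 to 0.0395), and all 4 passed with no filter (edgeR q 0.00398 to 0.0329). Among other fits, calls ended with the compared groups only for the CDK inhibitor, p53 target, histone and endothelial lists (fry q 0.0629 to 0.124) and IL1B (edgeR q = 0.07998), and with all 37 libraries for IL1B (edgeR q = 0.0825). Fry calls were gained by the lysosome, smooth muscle, epithelial and leukocyte lists with all 37 libraries and the smooth muscle list without late-passage 2 (q 0.00753 to 0.0259).

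Responses of 2 comparisons were set against each other by testing the difference of their log2 fold changes, the first minus the second, ± its standard error, in 1 edgeR fit. Every gene named passed. HUVEC against HAEC differed in 5436 genes, 2678 of them with the higher value in HUVEC (49.3%) and 2758 with the lower. With all 37 libraries the counts were 274 and 456 (37.5%). MMP1 (2.81 ± 0.05) was higher, as was CDKN2A (1.32), and SULF1 (-4.68 ± 0.09) lower. In IMR-90 radiation minus replicative exhaustion differed in 1500 genes one way and 1595 the other, with POSTN (1.57 ± 0.06) above 0 and TENM1 (ENSG00000009694, -3.60 ± 0.13) below. Among fixed genes GDF15 (2.13) was above 0 and CDKN2A (-0.90) below. The count was 295 with all 37 libraries and 1216 and 1145 without irradiated 1 and 2.

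Between WI-38 and IMR-90 the strain and the kind of library changed together and cannot be told apart. For radiation, 3235 genes lay above 0 and 4068 below: ATP8B4 (ENSG00000104043, 8.22 ± 0.30), CXCL8 (10.86) and IL1B (8.05) above, TENT5C (ENSG00000183508, -7.55 ± 0.25), TK1 (-5.28) and MKI67 (-5.18) below. For replicative exhaustion, 1684 lay above and 2670 below, with MMP3 (5.22 ± 0.29) and CXCL8 (5.12) above and PSG5 (ENSG00000204941, -7.71 ± 0.32) and MKI67 (-3.17) below. The total was 6850 with all 37 libraries and 2836 to 2915 without 1 of the control libraries. HRAS minus the first doxorubicin response gave 6355 genes above 0 and 4101 below, among them MMP10 (ENSG00000166670, 9.59 ± 0.30) and IL1B (8.40) above and CYTL1 (ENSG00000170891, -6.17 ± 0.22) below. All 37 libraries in the fit moved the median of all genes by -0.11.

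Within the second WI-38 set, radiation minus replicative exhaustion gave 1430 genes above 0 (67.9%) and 675 below, with HEPH (10.61 ± 0.41) and CXCL8 (6.93) above and CST4 (-8.97 ± 0.77) below. The share above was 49.3% of 6558 with all 37 libraries and 54.9% of 3537 by the Wald test. The total was 3190 with no filter and 1121 to 1340 without 1 of the control libraries. Radiation minus the doxorubicin repeat gave 468 genes above 0 (59.5%) and 318 below, with OAS1 (5.18 ± 0.51) above and TK1 (-3.65 ± 0.28) and MKI67 (-2.80) below. The share above was 48.4% of 5286 with all 37 libraries and 49.5% of 1931 by the Wald test. The total was 2102 with no filter, 475 with the compared groups only and 368 to 2627 with 1 library left out. The doxorubicin repeat minus the first experiment, which also sets the 2 kinds of library against each other, gave 868 genes above 0 and 743 below, with the histone gene H3C14 (7.37 ± 0.31) and MKI67 (3.42) above and FABP3 (-6.84 ± 0.38), HMGCS1 (-3.49) and CDKN1A (-1.65) below. The total was 4151 with all 37 libraries, 2929 by the Wald test, and 989 to 1071 without any 1 library of the first set's controls or doxorubicin group.

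**Figure D1:**
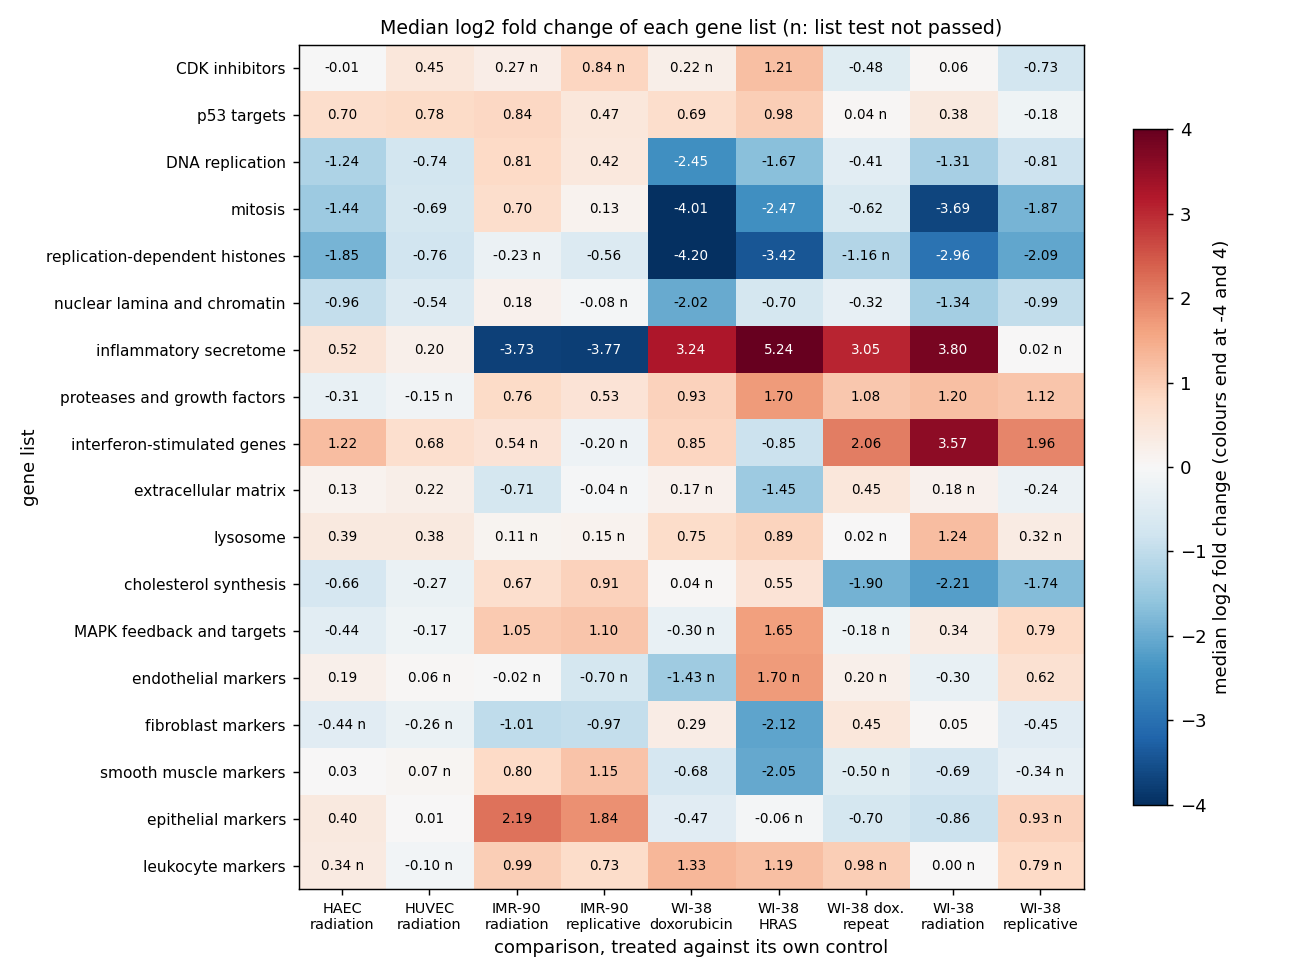
Median log2 fold change of each of the 18 gene lists (vertical axis) in the 9 comparisons (horizontal axis), red above 0 and blue below, with n where the fry test did not pass. The mitosis list lies below 0 in 7 comparisons and above 0 in both IMR-90 ones.

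**Figure D2:**
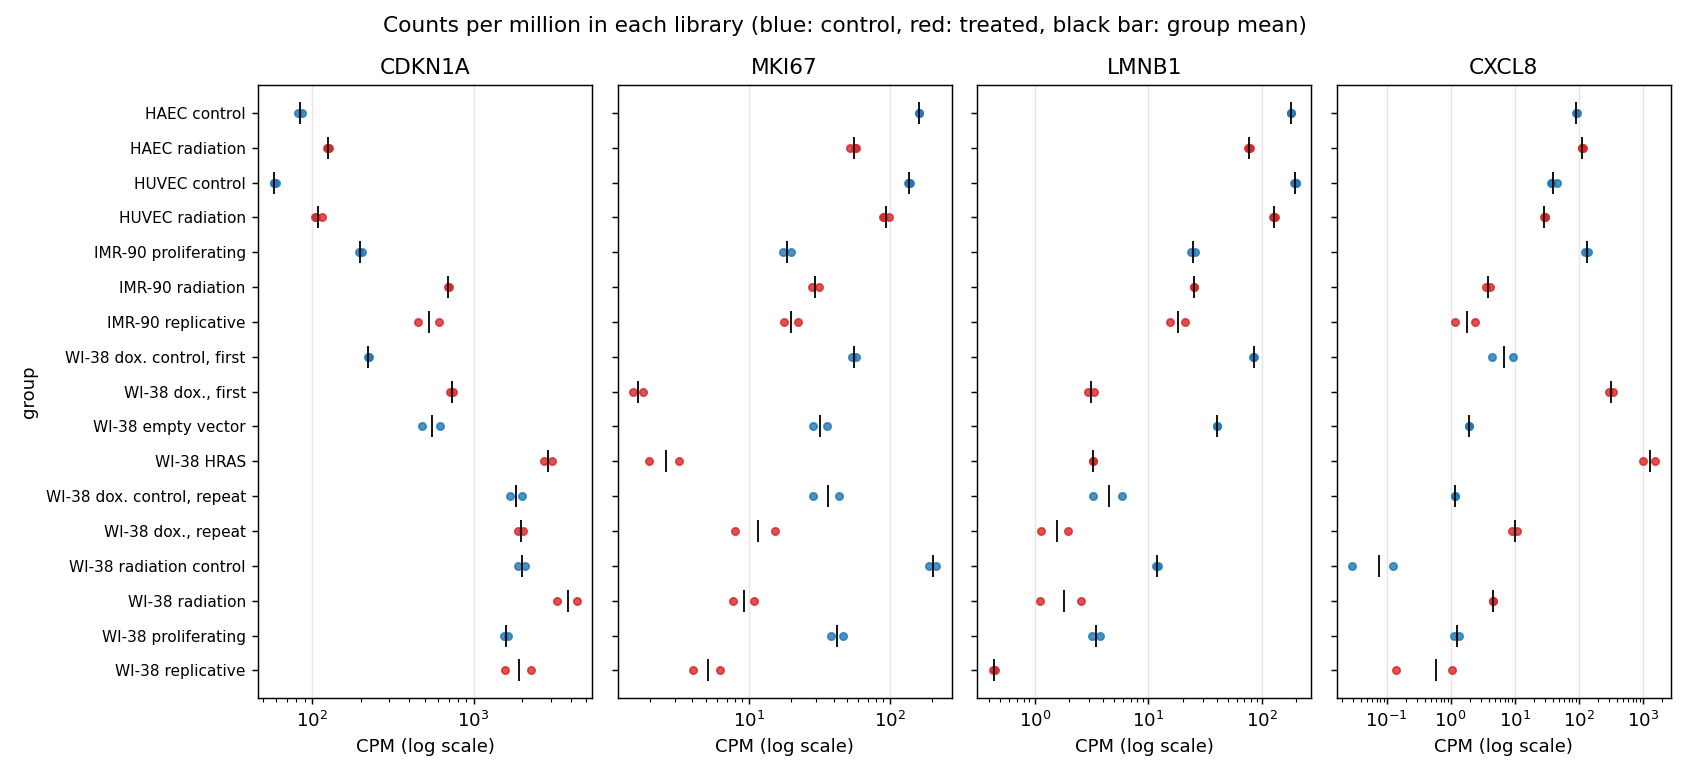
CPM of CDKN1A, MKI67, LMNB1 and CXCL8 in each library (horizontal log axes) by group (vertical axis), controls in blue, treated in red, black bars at group means. MKI67 fell in 7 comparisons, rose in irradiated IMR-90 and did not pass in late-passage IMR-90.

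Of 23653 genes tested in all 9 comparisons, 24 rose in each and 13 fell in each. The product of the shares called would leave 9.35e-04 and 4.15e-04 by chance, although comparisons that share cells or controls are not independent. Among those that rose, with the range of log2 fold changes, were PTCHD4 (ENSG00000244694, 1.41 to 4.17), a target of p53, DIO2 (ENSG00000211448, 1.00 to 3.89) and TNFSF13B (ENSG00000102524, 0.79 to 2.22). Those that fell included H1-4 (-3.55 to -0.70), H1-3 (-5.42 to -0.38) and CBX2 (ENSG00000173894, -2.92 to -0.34). Genes that rose in all 9 numbered 15 without doxorubicin repeat control 1 and 14 without early-passage WI-38 1 or 2, and genes that fell numbered 5 and 8 without doxorubicin repeat control 1 and 2, 3 without doxorubicin repeat 1 or 2 or with all 37 libraries, and 8 with the compared groups only. Across genes log2 fold changes had a Pearson r of 0.707 between HAEC and HUVEC, 0.477 between both doxorubicin experiments, -0.12 between radiation in IMR-90 and in WI-38, and 0.355 between replicative exhaustion in both strains, of 36 pairs computed.

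**Figure D3:**
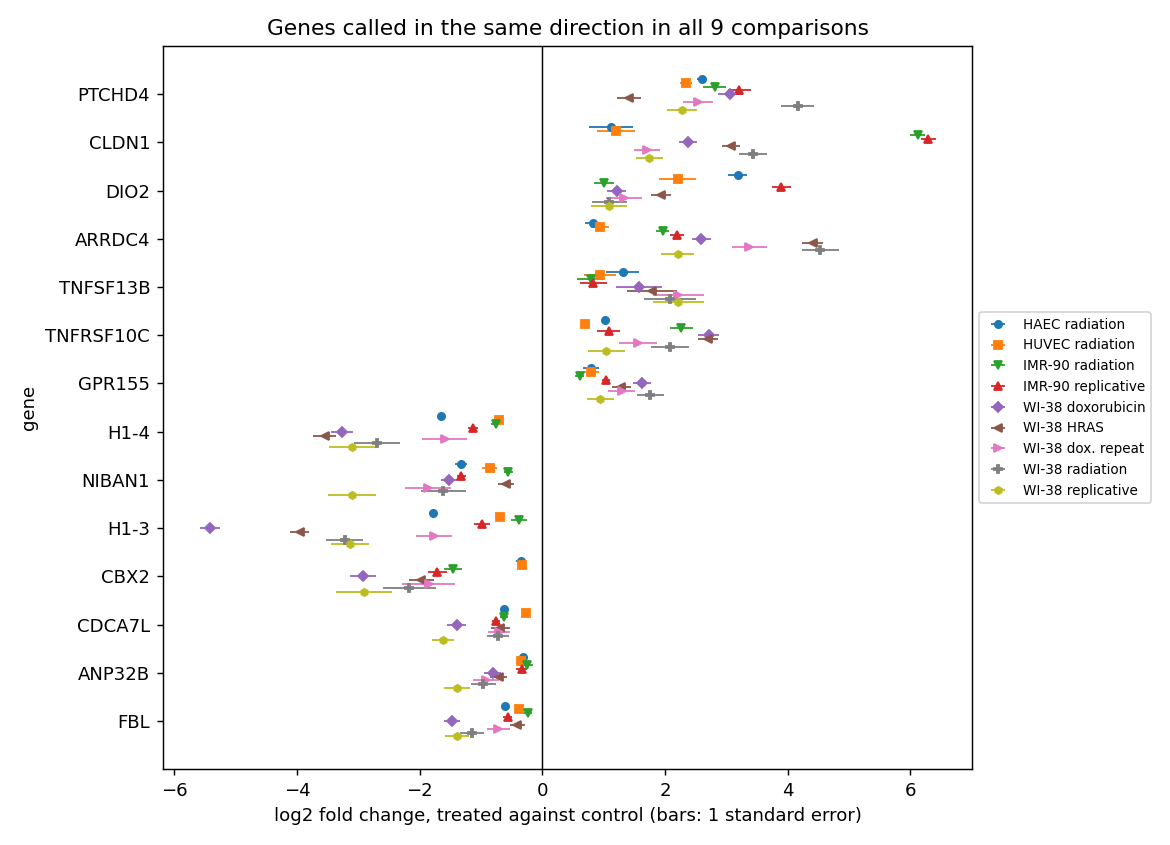
Log2 fold change ± 1 SE (horizontal axis) of 14 genes with a symbol that rose or fell in all 9 comparisons (vertical axis), 1 point per comparison. PTCHD4 lies between 1.41 and 4.17, and H1-4 between -3.55 and -0.70.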

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

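Chosen after the result was seen were the tests of exchanged labels, of a slow IMR-90 control and all of the doxorubicin repeat. So were the 4-fold limit and the placing of other HAEC libraries in the test of HRAS reads. The others were written before. Each of the 8 tests of a difference between responses found genes that differed: 5436 between HUVEC and HAEC, 3095 between radiation and exhaustion in IMR-90, 7303 between radiation in WI-38 and in IMR-90, 4354 between exhaustion in both, 10456 between HRAS and doxorubicin, 2105 between radiation and exhaustion in WI-38, 786 between radiation and the doxorubicin repeat, and 1611 between both doxorubicin experiments. The 6 HUVEC libraries allow 10 splits, too few for a share under 0.05. Only the real split, 1 of 10, gave 10637 called genes and the others 0.

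Cell-cycle genes were higher in irradiated IMR-90 than in the proliferating cells, and less so at late passage (mitosis 12 up, 3 down of 28). Labels exchanged between control and 1 treated group are in part argued against by CDKN2A and p53 targets (medians of 0.47 or more). The inflammatory secretome, higher in 6 comparisons, went the other way (medians -3.73 and -3.77). A first version, on library correlations, was replaced after its run as it assumed that treated groups resemble each other. WI-38 RNA in the control libraries is argued against, on few genes. Of the 4 that separate the strains 8-fold, 100% lay nearer IMR-90 in both, and of 8 at 4-fold, tried afterwards, 75%. Also open is that the control culture divided little. Its log2 median over 55 cell-cycle genes was -1.45 from WI-38 controls of its library kind (-1.90 from the doxorubicin control, -0.86 from empty vector). Irradiated IMR-90 was also 2.17 above doxorubicin-treated WI-38, so a slow control may account for only part. A biological difference between strains or treatments was not tested.

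With all 37 libraries scaled together, MMP3 and IL1B stood at 9.33 and 1.41 CPM in HAEC control 1, against means of 0.142 and 0.0662 in the other 4 HAEC libraries. Reads of the HRAS libraries, where both are abundant, are a candidate source: of 8 genes with at least 200 CPM there and under 0.1% of that in the other HAEC libraries, 100% were highest in this library, 6 of them besides MMP3 and IL1B (SLC6A15, EREG, TAGLN3, STC1, TNFSF15 and SERPINB2), at 0.133% to 0.298% of their source level, median 0.204%. As the rule itself favours a library left out of it, each of the other 4 was put in its place afterwards, which gave 0% to 55.6% of 8 or 9 genes and a median of at most 0.0131% of the source level. For other fibroblast RNA 0 genes met the rule, so that it cannot be told apart. No biological explanation was tested.

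In the doxorubicin repeat cell-cycle genes fell less than in the first experiment. A larger spread is argued against by slopes of repeat on first fold changes over 55 genes. They differed by at most 0.0918 between the 4 library pairs and lay 0.839 below 1 for all libraries. A first version, on that slope alone, restated the pattern and was replaced. The kind of library is argued against by the radiation comparison of the same set, whose mitosis median was -3.69. Control cells that divided less may account for the smaller fall in the repeat. Their cell-cycle median lay at -1.90 from the radiation control, and at -2.01 and -1.76 in the single libraries. The early-passage control lay at -1.68 too, and the mitosis list still fell against it by 1.87 on the log2 scale, so this explanation stays open and incomplete, as does a difference in the treatment itself, which was not tested.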

How the results depend on the processing

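The alternatives that leave out both IMR-90 comparisons and that reverse the order of the design columns were chosen only after the result was seen, and all others before; where the cause of a change is not given, the cause was not tested. Counts of called genes stayed within 1.5 times under DESeq2 size factors in all 17 comparisons and differences. With no filter they moved for the doxorubicin repeat (3136), WI-38 radiation minus exhaustion (3190) and radiation minus the doxorubicin repeat (2102). By DESeq2's Wald test they were 3576, 3537 and 1931 for these, and 2929 for the repeat minus the first doxorubicin experiment. With the compared groups only the first doxorubicin experiment gave 12697, radiation minus the repeat 475, and 8 genes fell in all 9 comparisons.

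With all 37 libraries in 1 fit the counts were 3941 in HAEC, 3260 in HUVEC, 9126 and 9318 in irradiated and late-passage IMR-90, 6468 in the doxorubicin repeat, and 10826 and 9148 in irradiated and late-passage WI-38. For the differences they were 730 for HUVEC minus HAEC, 295 for IMR-90 radiation minus exhaustion, 6850 for exhaustion in WI-38 minus IMR-90, 6558 for WI-38 radiation minus exhaustion, 5286 for radiation minus the repeat and 4151 for the repeat minus the first experiment, and 3 genes fell in all 9 comparisons. Both doxorubicin experiments in 1 fit gave 4560 genes. A call in at least 8 comparisons left 68 genes higher and 44 lower. Leaving out HUVEC gave 39 and 20, HRAS 41 higher, the doxorubicin repeat 52 and 35, and both IMR-90 comparisons 40 and 44.

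With each library left out in turn, counts that moved by over 1.5 times ranged over 4485 to 4745 for the first doxorubicin experiment, 612 to 2501 for the doxorubicin repeat, 2572 to 6457 for irradiated WI-38, 1881 to 4209 for late-passage WI-38. Among differences they ranged over 1145 to 3452 for IMR-90 radiation minus exhaustion, 2836 to 4901 for exhaustion in WI-38 minus IMR-90, 1121 to 2948 for WI-38 radiation minus exhaustion, 368 to 2627 for radiation minus the doxorubicin repeat, 989 to 2253 for the repeat minus the first doxorubicin experiment. Shared genes ranged over 14 to 25 higher and 3 to 14 lower, and passing list tests over 112 to 124.

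Replicate numbers were not taken to pair the samples, as neither the labels nor 3 correlated pairs show it: the correlation of deviations between same-numbered HUVEC libraries was -0.0629, -0.321 and -0.324, and none correlated best with its own number. The other comparisons had only 2 pairs, with 0.717 with HRAS, 0.504 in irradiated WI-38, 0.114 in irradiated IMR-90 and -0.212 to 0.0372 elsewhere. The replicate block kept all counts of called genes within 1.5 times. With the block the CDK inhibitor, protease, interferon, matrix, endothelial and smooth muscle lists in HAEC (q 0.0751 to 0.295), the histone list in late-passage IMR-90 (q = 0.117), the mitosis list in the doxorubicin repeat (q = 0.0683) and the CDK inhibitor list in irradiated WI-38 (q = 0.0577) did not pass fry, the interferon list in irradiated IMR-90 (q = 0.0391), the endothelial list in the first doxorubicin experiment (q = 0.0236), the endothelial and epithelial lists with HRAS (q 0.0229 to 0.0495) and the MAPK target list in the doxorubicin repeat (q = 0.0449) passed, IL6 in HUVEC did not pass edgeR (q = 0.0512), and CDKN2B in the repeat (q = 0.0264) and in late-passage WI-38 (q = 0.0407) did.

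The 162 list tests kept direction and side of the threshold in 159 cases with size factors, 152 with no filter, 145 with the block, 136 with the compared groups only, 132 with all 37 libraries and all 162 with the design columns reversed, where the CDK inhibitor list of late-passage IMR-90 changed most, from q = 0.204 to 0.407. Directions of fry reversed for 15 lists, of which only the smooth muscle list of irradiated IMR-90 had passed; the values given are medians, whose sign can differ from the test. Brackets name the setting; ranges are over single libraries left out, with those that reversed the direction in brackets. In late-passage IMR-90 the lysosome median was 0.16 (size factors), 0.19 (all 37 libraries) and -0.0025 to 0.22 (late-passage 1). The CDK inhibitor median was 0.84 (replicate block), 0.89 (all 37 libraries) and 0.79 to 0.90 (late-passage 1 or 2). In HUVEC the endothelial median was 0.0481 (no filter). The fibroblast median was -0.48 to -0.0123 (control 3 or irradiated 3). In the first doxorubicin experiment the CDK inhibitor median was 0.22 (replicate block) and 0.23 (groups only). The cholesterol median was 0.0375 (replicate block), 0.0468 (groups only) and -0.0055 to 0.0728 (doxorubicin 1). The MAPK target median was -0.29 (groups only) and -0.33 (all 37 libraries). In irradiated IMR-90 the CDK inhibitor median was 0.26 (groups only) and 0.31 (all 37 libraries). The endothelial median was -0.0277 (groups only) and -0.21 to 0.20 (proliferating 1). The smooth muscle median was 0.77 to 0.81 (proliferating 2). In the doxorubicin repeat the p53 target median was 0.0248 (groups only) and -0.0377 to 0.16 (control 1). The lysosome median was -0.31 to 0.19 (doxorubicin 1). In irradiated WI-38 the leukocyte median was -0.28 to 0.56 (control 2). In late-passage WI-38 the inflammatory median was -0.79 to 0.18 (late-passage 2). The leukocyte median was -1.05 to 2.64 (early-passage 1). Among genes, in HAEC CDKN2A was 0.0027 (replicate block), 0.0346 (all 37 libraries) and -0.11 to 0.11 (control 1 or irradiated 1 or 3). MMP3 was -6.00 to 0.0385 (control 1). In irradiated IMR-90 LMNB1 was -0.0326 to 0.10 (proliferating 1). In late-passage IMR-90 MKI67 was -0.0713 to 0.26 (late-passage 1). In the doxorubicin repeat CDKN1A was -0.0234 to 0.21 (control 1). GLB1 was -0.0787 to 0.46 (doxorubicin 1). In irradiated WI-38 CDKN2A was -0.10 to 0.0265 (control 2). In late-passage WI-38 CDKN1A was -0.0319 to 0.55 (late-passage 2). CDKN2A was -0.15 to 0.11 (late-passage 1 or early-passage 1). MDM2 was -0.17 to 0.0642 (late-passage 2). Genes at 0 counts in a group allow only a lower bound of their fold at this depth.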
